A study of Homo sapiens with 10 samples.

How the data were processed

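RNA from MCF7 cells was sequenced in 10 libraries, 2 from each of 5 groups: the control vectors pGIPZ and pLKO, which per the series description carry non-targeting shRNA, and cells stably expressing an shRNA against USP22, USP27X or USP51. Per the labels' protocols, cells were selected with puromycin at 2.5 µg/ml, grown in DMEM to about 75% confluence and lysed for RNeasy extraction with DNase treatment, and libraries were made with the TruSeq RNA kit. The submitters' processing notes name CASAVA 1.8.2, TopHat2 2.0.7, HTSeq 0.5.3p9 and the human genome build hg19, without giving each a role or order. The deposited files hold the count of reads per gene that the authors made, with no normalization in each library. The annotation and the strand setting used in counting are not given in the sources used here, and no reads were available to recount.

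Counts were analysed in R 4.3.3 with edgeR 4.0.16 and limma 3.58.1. Genes with too few counts for testing were removed with filterByExpr, which left 15070 genes, and libraries were scaled by TMM. All 10 libraries were fitted in a single quasi-likelihood model with 1 coefficient per group and robust dispersions, which left 5 residual degrees of freedom, a median of 4.8 prior degrees of freedom and a common biological coefficient of variation of 0.185. Each knockdown was compared with the mean of the pGIPZ and pLKO coefficients, then with each vector alone, and the vectors and the knockdowns were compared with each other, 13 contrasts in all. Within each contrast p-values were adjusted by the Benjamini-Hochberg method and genes with an adjusted p under 0.05 were called. A gene was said to differ from both vectors when it was called in the same direction against each alone. Levels are counts scaled to library size (CPM) with TMM factors, as mean and SD of 2 libraries. Log values used a prior count of 2. For a gene at 0 counts in a group, the fold is a lower bound that takes 3 counts over the 2 libraries of the group.

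The comparisons, the 25 gene lists, the rule for naming genes and most alternatives were fixed before the data were examined. The lists were the deubiquitinating module and paralogues, SAGA core subunits, H2B ubiquitination machinery with other H2B deubiquitinases, replication-dependent histones, estrogen receptor targets, luminal identity, mesenchymal and basal genes, DNA replication and G1/S, G2/M and mitosis, cell-cycle inhibitors, p53 targets, MYC targets and ribosome biogenesis, cytosolic ribosomal proteins, mitochondrial oxidative phosphorylation, glycolysis and hypoxia, cholesterol biosynthesis, unfolded protein response and ATF4 targets, interferon-stimulated genes, NF-kB and inflammatory genes, immediate early and AP-1 genes, apoptosis regulators, cell adhesion and matrix, fibroblast markers, blood and endothelial markers, and basal-like breast line markers. Each list was tested against all other genes with camera at its preset correlation of 0.01 and again with a correlation estimated from the data, and its members alone with fry, with Benjamini-Hochberg adjustment over the 25 lists. The genes named were USP22, USP27X, USP51, ATXN7L3 and ENY2; the 8 highest and 8 lowest fold changes per knockdown among genes with a mean of at least 1 CPM that differed from both vectors; up to 4 members per list by smallest adjusted p; the 5 highest and 5 lowest in each other contrast; and up to 6 per direction called in all 3 knockdowns. Genes with locus, small RNA, antisense or pseudogene names were passed over, while open reading frame names were kept. MIF and MIR30A in the account of the library sets, LIN28B, MTAP, and VIM in the comparison of vectors were singled out after their values were seen.

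Genes whose exons overlap another gene of the count files on the opposite strand were found from exon positions in GENCODE 29, a different genome build. They were linked to the counts by gene name only. The overlap of called genes between knockdowns was set against independent lists, against 20 simulated data sets with unchanged groups and shared controls, and against splits that gave each knockdown its own control vector. The tests were tested on simulated data with 100 genes changed 2-fold and 100 changed 4-fold. For USP27X against the average of both vectors edgeR recovered 53 and 85 of these, and DESeq2 61 and 84. The alternatives were DESeq2 1.42.0 in place of edgeR, other scalings, no filter on low counts, each vector alone or the 4 control libraries as 1 group, fewer libraries in the fit, a replicate block, and each library left out in turn. A replicate block within each library set, and testing only genes with no opposite-strand overlap, were added after the data were seen, as were fits to the libraries of a set alone. Tables were handled with Python 3.11.15 and pandas 2.3.3, and figures drawn with matplotlib 3.10.9. No library was left out.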

Results

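Gene expression was profiled by RNA-seq in MCF7 cells, an estrogen receptor-positive line of luminal breast cancer, after stable lentiviral expression of an shRNA against USP22, USP27X or USP51. These genes encode related ubiquitin proteases that remove ubiquitin from histone H2B, and the series deals with how ATXN7L3 and ENY2, subunits of the deubiquitinating module of the SAGA coactivator complex, act with several such enzymes. The comparisons ask how loss of each enzyme changes the transcriptome of these cells. The 10 libraries formed 5 groups of 2, namely the control vectors pGIPZ and pLKO and the knockdowns shUSP22, shUSP27x and shUSP51. Total gene counts were 16944887 and 15963100 in the pGIPZ libraries, 17068064 and 22183061 in pLKO, 15225868 and 12355127 in shUSP22, 18884789 and 18259815 in shUSP27x and 19057923 and 21751266 in shUSP51. After genes with low counts were removed, 15070 genes were tested.

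The libraries fell into sets of 4 and 6 that went with the control vectors. MIF, which encodes a cytokine, had 4693 to 7253 counts in each pGIPZ and shUSP22 library and 0 counts in each pLKO, shUSP27x and shUSP51 library. MIR30A, a microRNA gene, had 883 to 1196 counts in the first set and 0 in the second. In all, 83 genes had 3 counts or fewer in every library of the first set and a mean above 1 CPM (counts scaled to library size) in the second, and 12 genes showed the reverse. Of the 84 of these 95 genes that could be matched to an annotation, 39.3% had exons overlapping a gene on the opposite strand, against 23.1% of all genes tested. Replicate libraries of a group had Spearman correlations across genes of 0.98 to 0.986, different groups within a set 0.965 to 0.985, and libraries of different sets 0.94 to 0.974. Replicates differed by more than sampling noise, with a chi-square of 10.5 to 49.3 per degree of freedom. The labels do not say whether replicates were separate cultures, so p-values measure only the spread between libraries, which may be technical. Nor do they say which vector carried each shRNA. Each knockdown was therefore set against the average of both vectors. Where a gene or list named for a knockdown lost its call against the vector of the knockdown's own set alone, that value is given beside it, and it is also given for the counts of called genes and for some of the folds that moved.

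**Figure D1:**
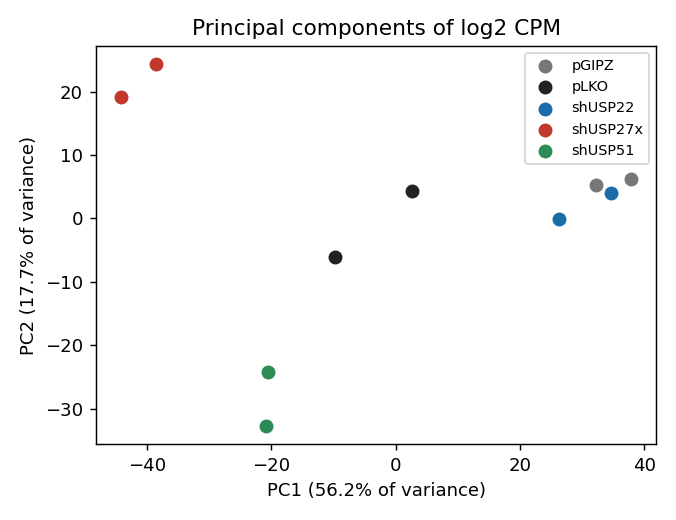
Principal components of log2 CPM over 9982 genes, with 1 point per library coloured by group. The first component (x axis, 56.2% of the variance) held the pGIPZ and shUSP22 libraries at 26.3 to 37.9, the pLKO libraries at -9.73 and 2.71 and the shUSP27x libraries at -44.2 and -38.5; the second (y axis, 17.7%) separated shUSP27x at 19.2 and 24.3 from shUSP51 at -32.7 and -24.2.

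Each targeted mRNA was lowest in its own knockdown. USP22 measured 86.3 ± 15.3 CPM (SD, n = 2) in shUSP22, against 361 ± 2.1 CPM in pGIPZ and 413 ± 31.7 CPM in pLKO, a 4.47-fold fall (log2 fold change -2.16, SE 0.15, edgeR adjusted p = 3.81e-04). USP27X measured 2.58 ± 0.459 CPM in shUSP27x, against 4.80 ± 0.666 CPM in pGIPZ and 4.52 ± 0.539 CPM in pLKO, a 1.8-fold fall (log2 fold change -0.85, SE 0.25, edgeR adjusted p = 0.026). USP51 measured 0.364 ± 0.00261 CPM in shUSP51, against 2.71 ± 0.357 CPM in pGIPZ and 1.77 ± 1.25 CPM in pLKO, a 5.88-fold fall (log2 fold change -2.56, SE 0.52, edgeR adjusted p = 0.00871) that rested on 7 and 8 counts in the knockdown libraries. Against pLKO alone the adjusted p was 0.0895 for USP27X and 0.0576 for USP51 (edgeR). The USP27X call was lost without pGIPZ_1, shUSP27x_1 or shUSP27x_2 (edgeR adjusted p = 0.0791, 0.0612 and 0.163), and the USP51 call without shUSP51_1 or shUSP51_2 (0.0637 and 0.0675). Against the average of both vectors ATXN7L3 and ENY2 passed the test in none of the 3 knockdowns, with edgeR adjusted p of 0.129 to 0.749 for ATXN7L3 and 0.138 to 0.67 for ENY2. ENY2, whose count is uncertain because it overlaps an opposite-strand gene, passed in the USP27X knockdown against pGIPZ alone (edgeR adjusted p = 0.0366). USP51 in the USP27X knockdown stood at 1.05 ± 0.37 CPM (log2 fold change -1.03, SE 0.46, edgeR adjusted p = 0.103), a call made only without pLKO_2 (adjusted p = 0.0186).

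**Figure D2:**
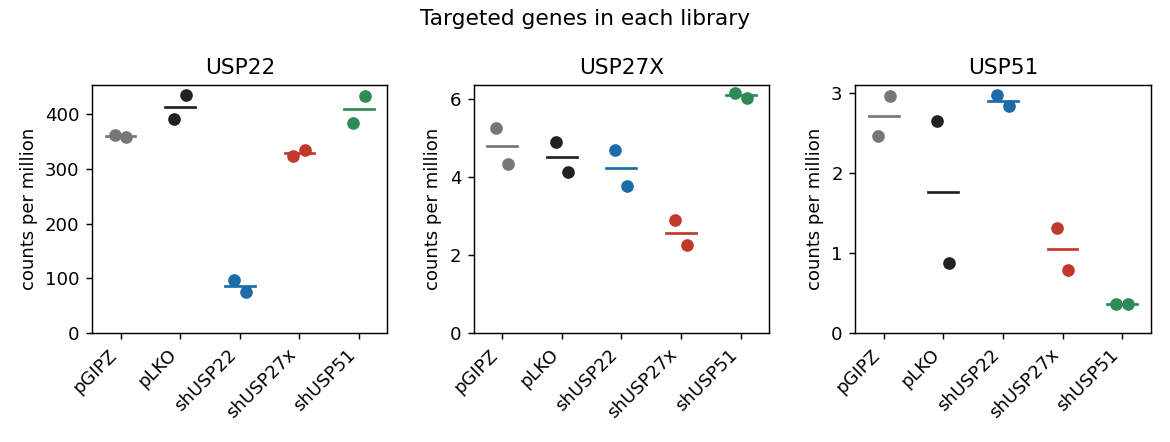
Scaled counts in CPM (y axis, from 0) of USP22, USP27X and USP51 in each of the 10 libraries, with 1 point per library and a bar at the mean of each group of 2. USP22 stood at 86.3 CPM in shUSP22 against 361 and 413 CPM in the control vectors, USP27X at 2.58 CPM in shUSP27x against 4.80 and 4.52 CPM, and USP51 at 0.364 CPM in shUSP51 against 2.71 and 1.77 CPM.

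The libraries of the control vectors differed widely. MIF stood at 415 ± 21 CPM in pGIPZ and was at least 5440-fold lower in pLKO, while CIDEB, a regulator of lipid droplets, stood at 41.2 ± 3.15 CPM in pLKO and was at least 468-fold lower in pGIPZ. C19orf33 was at least 468-fold and HYI at least 154-fold lower in pLKO, and DENND1C at least 141-fold lower in pGIPZ. VIM, which encodes the mesenchymal filament protein vimentin and was singled out after its values were seen, measured 244 ± 52.9 CPM in pGIPZ and 32.1 ± 24.1 CPM in pLKO (7.58-fold, log2 fold change 2.92, SE 0.48, edgeR adjusted p = 0.00984). CIDEB, DENND1C and HYI overlap a gene on the opposite strand, so their counts are uncertain. Lower bounds on a fold change take a gene at 0 as 3 counts over the 2 libraries of the group, and cover counting error only. In total 1041 genes were higher and 995 lower in pGIPZ than in pLKO (edgeR). Without pGIPZ_1, pGIPZ_2 or pLKO_1 the total fell to 430, 125 or 526 genes.

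Several gene lists differed between the control vectors. Higher in pGIPZ and never lower were 7 of 21 histone genes, 9 of 31 G1/S genes, 2 of 32 G2/M genes, 7 of 23 mesenchymal and basal genes and 4 of 10 basal-like markers, or 9, 12, 2, 11 and 6 adjusted over the list alone (camera adjusted p = 6.99e-04, 7.87e-05, 8.89e-04, 8.89e-04 and 0.00405). Lower and never higher were 6 of 32 estrogen receptor targets, 5 of 21 luminal genes, 4 of 29 interferon-stimulated genes and 5 of 25 immediate early genes, or 7, 10, 5 and 7 over the list alone (camera adjusted p = 9.23e-04, 8.89e-04, 6.65e-04 and 0.0107). MYC targets were higher in 2 of 30, or 0 over the list alone (camera adjusted p = 0.0382). With an estimated correlation the adjusted p was 0.571 for the mesenchymal and basal-like lists and 0.85 for the other 8.

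In the USP22 knockdown few genes passed the main test, which did not use replicate numbers as pairs. USP22 was the 1 gene that differed in the same direction from both vectors. Against pGIPZ, the vector of its own library set, USP22 fell 4.18-fold (log2 fold change -2.06, SE 0.16, edgeR adjusted p = 0.00233), and 0 genes were higher and 1 lower. At an unadjusted p below 0.05, 221 genes differed from pGIPZ by edgeR, fewer than the 754 that 5% of the genes tested would give. The test was thus conservative here, and the count does not show that other genes were unchanged. DESeq2 also called 0 higher and 1 lower, with 154 genes at an unadjusted p below 0.05. In a fit to the libraries of its own set alone 691 genes reached that level. With a replicate block that fit called 744 higher and 571 lower. A block within each set in the full fit called 0 and 1. The labels do not say that replicate numbers mark pairs. In data simulated for this comparison, edgeR recovered 34 of 100 genes changed 2-fold and 82 of 100 changed 4-fold, so that many changes of 2-fold would have been missed. Against the average of both vectors 19 genes were higher and 9 lower, among them TYMS, a thymidylate synthesis enzyme, at 33.7 ± 2.12 CPM against 24.2 ± 1.87 in pGIPZ and 4.70 ± 0.203 in pLKO (3.16-fold, edgeR adjusted p = 0.00303, and 1 against pGIPZ alone). TYMS overlaps an opposite-strand gene, and its call was lost without shUSP22_1 or shUSP22_2 (adjusted p = 0.055 and 0.0751). Without pGIPZ_1, pGIPZ_2, shUSP22_1 or shUSP22_2 the total of 28 genes fell to 13, 9, 8 or 8. The count of genes that differed from both vectors fell to 0 without shUSP22_2.

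In the USP22 knockdown against pGIPZ, USP22 itself was the 1 list member called by edgeR, over all genes or adjusted over the list alone. Over all genes, called or not, camera with its preset correlation placed the estrogen receptor target genes (median log2 fold change 0.27, adjusted p = 7.38e-08), the luminal identity genes (0.23, adjusted p = 2.54e-09) and the p53 targets (0.11, adjusted p = 0.0276) above other genes. It placed the mesenchymal and basal genes (-0.19, adjusted p = 0.0148) and the cytosolic ribosomal proteins (-0.10, adjusted p = 4.61e-04) below. A group of 176 genes described below, near 0 in shUSP51, had a median of 0.723 of pGIPZ in shUSP22 (0.477 in shUSP22_1 and 0.96 in shUSP22_2). On that scale pGIPZ_1 stood at 0.78 and pGIPZ_2 at 1.22, so the lower level rests on shUSP22_1. The deubiquitinating module also passed (camera adjusted p = 0.00225), with a median of 0.07 and a mean of -0.17. This list includes USP22, the targeted gene, so a pass here or below does not show that its other members moved. With an estimated correlation the adjusted p of these 6 lists was 0.526 to 0.931. Against the average of both vectors, camera passed the deubiquitinating module (1 of 9 members lower, USP22, adjusted p = 0.0122), the DNA replication and G1/S genes (1 of 31 higher, adjusted p = 6.44e-04), the G2/M genes (0 of 32 called, adjusted p = 0.0027) and the interferon-stimulated genes (0 of 29 called, adjusted p = 7.67e-06). The estimated-correlation adjusted p of each was 0.928, and by fry, which tests the members alone, the adjusted p was 0.26, 0.722, 0.873 and 0.722. Against pGIPZ alone the last 3 had adjusted p of 0.661, 0.97 and 0.333, with the G1/S genes in the opposite direction. The module call was lost without pLKO_1 or shUSP22_2 (adjusted p = 0.054 and 0.204) and the G2/M call without shUSP22_2 (0.0934). The other 21 lists did not pass the test.

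In the USP27X knockdown nearly every listed gene of the cell division cycle was lower. All 21 measured replication-dependent histone genes, 29 of 31 DNA replication and G1/S genes and all 32 G2/M and mitosis genes were lower, and 0 were higher. HIST1H2AG fell 3.9-fold, to 68.4 ± 1.34 CPM from 331 ± 13.0 in pGIPZ and 215 ± 0.918 in pLKO (log2 fold change -1.96, SE 0.15, edgeR adjusted p = 7.12e-05). INHBA, which encodes a subunit of activin and inhibin, rose 29.1-fold, to 109 ± 24.1 CPM from 1.47 ± 0.237 in pGIPZ and 9.46 ± 1.67 in pLKO (log2 fold change 4.86, SE 0.21, edgeR adjusted p = 5.04e-06). Overall counts were 2583 higher and 2937 lower of 15070 genes, and 761 higher and 1123 lower against pLKO alone, the vector of its library set. In a fit to the libraries of that set alone 233 were higher and 347 lower, or 1150 and 1292 with a replicate block. In all 671 genes were higher and 1022 lower than both vectors.

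Other genes with large increases against both vectors were as follows. GLRA3, a glycine receptor subunit, rose 26.7-fold, to 117 ± 21.6 CPM from 3.42 ± 0.197 in pGIPZ and 5.56 ± 0.689 in pLKO (edgeR adjusted p = 3.17e-06). COL5A2, a fibrillar collagen chain, rose 19.9-fold, NT5E, the ecto-nucleotidase CD73, 18.8-fold, and MSMB, a secreted prostatic protein, 17.5-fold, with edgeR adjusted p of 1.33e-04, 2.65e-04 and 6.00e-05. Against pLKO alone INHBA rose 11.5-fold, GLRA3 21-fold and MSMB 18.3-fold (edgeR adjusted p = 3.04e-04, 7.72e-05 and 6.85e-04), while COL5A2 and NT5E rose 11.3-fold and 9.74-fold (0.00271 and 0.00549). C14orf182 rose 17.0-fold, while MC4R and OLFML3 rose 41.9-fold and 16.6-fold at 11.8 ± 6.38 and 14.3 ± 10.0 CPM, or 9.64-fold, 14.2-fold and 8.06-fold against pLKO alone (edgeR adjusted p = 0.00231, 0.00839 and 0.0443). The MC4R log2 fold change of 5.39 became 6.28 without pLKO_1 and 4.68 without shUSP27x_1, and that of OLFML3 went from 4.05 to 5.08 and 3.06. At the other end were genes with 0 counts in both shUSP27x libraries. The 8 named here belong to a group of 176 genes described below that were also near 0 in shUSP51 and differed between the vectors, with pLKO to pGIPZ ratios of 0.108 to 0.214 for these 8. SLC4A4, a bicarbonate transporter, was at least 62.3-fold lower than in pGIPZ and at least 13.8-fold lower than in pLKO, and LGR5, a receptor of stem cells, at least 62.6-fold and 13.8-fold lower. BCL11A was at least 75.9-fold and 10.3-fold lower, and the transcription factor gene ETV1 at least 76.9-fold and 10.3-fold. KCNQ5, SYT14, BATF3 and FGF9 were also at 0, with bounds of 35.7-fold to 66-fold against pGIPZ and 5.59-fold to 10-fold against pLKO.

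The cell division genes fell further than other genes by camera, with adjusted p of 1.14e-24 for the histones, 6.24e-24 for the G1/S genes and 8.28e-30 for the G2/M genes. With an estimated correlation the adjusted p was 0.243 for each of the 3 lists, and by fry it was 0.0022. Adjusted over the list alone, 21, 30 and 32 members were lower. Against pLKO alone 20, 26 and 32 members were lower, with median log2 fold changes of -1.30, -0.91 and -1.29. PCNA, the DNA polymerase clamp, fell 3.06-fold, GINS1 of the replicative helicase 3.1-fold, and E2F8, a cell-cycle transcription factor, 3.55-fold, each with an edgeR adjusted p of 1.57e-04. TPX2, a spindle assembly factor, fell 2.78-fold, the spindle checkpoint kinases TTK and BUB1B 3.19-fold and 2.8-fold, and FOXM1, a mitotic transcription factor, 5.41-fold (edgeR adjusted p = 1.12e-04 to 3.05e-04). Among the histones HIST1H3H, HIST1H3B and HIST1H2BJ fell 3.58-fold, 4.16-fold and 4.71-fold. Histone genes have near-identical copies and FOXM1 overlaps an opposite-strand gene, so reads may not be fully separated from their neighbours.

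**Figure D3:**
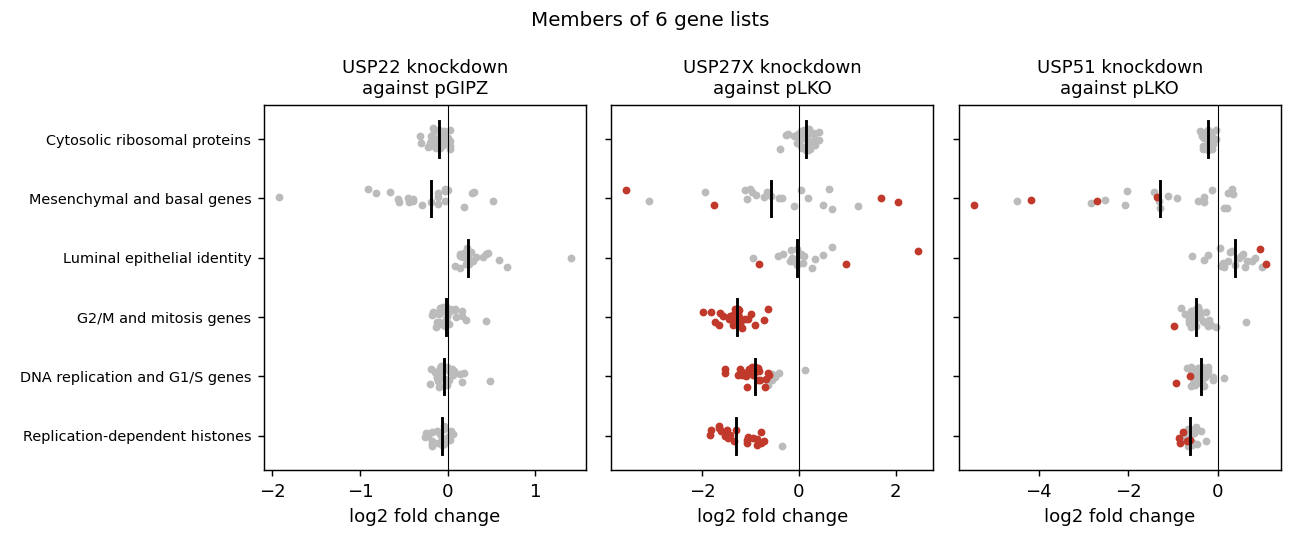
Log2 fold changes (x axis) of the measured members of 6 gene lists (y axis) in each knockdown against the control vector of its own library set, with 1 point per gene, red where the edgeR adjusted p was below 0.05 and grey otherwise, and a bar at the list median. In the USP27X knockdown the medians of the histone, G1/S and G2/M lists were -1.30, -0.91 and -1.29; in the USP51 knockdown they were -0.61, -0.37 and -0.49, and in the USP22 knockdown -0.07, -0.04 and -0.02.

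Regulators of the cycle and of cell death also moved. CDKN2C, which encodes the CDK inhibitor p18, fell 2.75-fold (edgeR adjusted p = 6.30e-04), while CDKN1A, which encodes the CDK inhibitor p21, rose 2.02-fold, to 339 ± 25.7 CPM from 148 ± 23.2 in pGIPZ and 191 ± 14.6 in pLKO (edgeR adjusted p = 0.00674, and 0.0659 against pLKO alone). Of 11 cell-cycle inhibitors 1 was higher and 3 lower, and the list did not pass camera (adjusted p = 0.493, and 0.671 with an estimated correlation). Of 24 apoptosis regulators 11 were higher and 1 lower (camera adjusted p = 0.0116, 0.298 with an estimated correlation and 0.00377 by fry). BIK, which promotes apoptosis, rose 2.97-fold (edgeR adjusted p = 8.55e-04) and BCL2, which opposes it, rose 2.41-fold, to 28.8 ± 5.46 CPM from 12.7 ± 2.2 in pGIPZ and 11.2 ± 2.42 in pLKO (edgeR adjusted p = 0.00107). The executioner caspase gene CASP7 rose 1.79-fold. Of 24 p53 targets 6 were higher and 3 lower, with no shift of the list (camera adjusted p = 0.827, and 0.938 with an estimated correlation).

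Genes of glycolysis and hypoxia, estrogen response and luminal identity rose in part. Of 30 glycolysis and hypoxia genes 12 were higher and 2 lower, or 13 and 2 adjusted over the list alone, with P4HA1, a collagen prolyl hydroxylase, up 2.08-fold, BNIP3, a mitophagy receptor, 2.31-fold, and VEGFA, an angiogenic factor, 2.37-fold (edgeR adjusted p = 3.78e-04, 5.00e-04 and 6.59e-04). Camera passed this list (adjusted p = 0.00426), but not without shUSP27x_2 (0.0638) nor with an estimated correlation (adjusted p = 0.637), and by fry the adjusted p was 0.0322. TFF3, a secreted trefoil peptide and estrogen target, rose 8.78-fold, to 72.4 ± 13.2 CPM from 5.19 ± 0.0458 in pGIPZ and 13.1 ± 1.73 in pLKO (edgeR adjusted p = 3.32e-05, and 5.54-fold with 7.36e-04 against pLKO alone). The receptor kinase gene RET rose 3.68-fold, cathepsin D gene CTSD 2.73-fold and the luminal keratin gene KRT19 2.52-fold (edgeR adjusted p = 1.68e-04, 0.00114 and 6.88e-04). Of 32 estrogen receptor targets 8 were higher and 5 lower, and of 21 luminal genes 5 were higher and 1 lower. Camera gave adjusted p of 0.0492 and 0.021 for these lists, both were 0.671 with an estimated correlation, and fry gave 0.107 and 0.0746. The estrogen call was lost without pGIPZ_2, pLKO_2, shUSP22_1, shUSP22_2 or shUSP27x_1 (adjusted p = 0.0958, 0.167, 0.0534, 0.0536 and 0.0801) and the luminal call without pLKO_2 or shUSP27x_2 (0.0839 and 0.0817). Against pLKO alone the camera adjusted p was 0.528 and 0.341.

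Some inflammatory, interferon and immediate early genes were also higher. Of 16 NF-kB and inflammatory genes 7 were higher and 1 lower, including ICAM1, an adhesion receptor, up 2.83-fold (edgeR adjusted p = 0.00262). Of 29 interferon-stimulated genes 7 were higher and 1 lower, or 6 and 1 adjusted over the list alone, with the exonuclease gene ISG20 up 6.86-fold and HERC5, a ubiquitin ligase, down 3.35-fold (edgeR adjusted p = 3.32e-05 and 0.00285). Of 25 immediate early genes 7 were higher and 1 lower, or 6 and 1 adjusted over the list alone, and FOS stood at 144 ± 62.5 CPM against 6.08 ± 1.8 in pGIPZ and 107 ± 71.3 in pLKO (edgeR adjusted p = 0.00451, and 0.649 against pLKO alone). Camera passed these lists at adjusted p of 0.021, 0.021 and 0.0324, with an estimated correlation the adjusted p was 0.637, 0.671 and 0.671, and by fry it was 0.043, 0.152 and 0.152. Against pLKO alone the interferon and immediate early lists did not pass (camera adjusted p = 0.431 and 0.3), and the NF-kB list did not against pGIPZ alone (0.107). The NF-kB call was lost without shUSP27x_2 (0.17), the interferon call without pLKO_2 or shUSP27x_1 (0.0902 and 0.465) and the immediate early call without pLKO_1 or shUSP27x_2 (0.172 and 0.338). Of 30 MYC target and ribosome biogenesis genes 10 were lower and 0 higher, among them the pyrimidine synthesis gene CAD, down 1.88-fold (edgeR adjusted p = 9.07e-04). This list passed camera (adjusted p = 0.012, 0.671 with an estimated correlation and 0.12 by fry) but not without pLKO_2 or shUSP27x_1 (0.0733 and 0.15) nor against pLKO alone (0.0717).

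Several subunits of chromatin complexes changed modestly. Of 18 SAGA core subunits 2 were higher and 5 lower (camera adjusted p = 0.493, and 0.744 with an estimated correlation). The acetyltransferase gene KAT2A fell 1.86-fold, to 24.4 ± 0.571 CPM from 48.1 ± 0.784 in pGIPZ and 43.0 ± 7.16 in pLKO, while its paralogue KAT2B rose 1.66-fold (edgeR adjusted p = 0.0014 and 0.00599). TAF9B fell 1.59-fold (edgeR adjusted p = 0.00286). ATXN7L3B, a paralogue of ATXN7L3, rose 1.92-fold, to 429 ± 12 CPM from 227 ± 7.58 in pGIPZ and 220 ± 4.06 in pLKO (log2 fold change 0.94, SE 0.11, edgeR adjusted p = 3.69e-04). It and USP27X were the 2 of 9 members of the deubiquitinating module called, and of 19 genes of H2B ubiquitination and other H2B deubiquitinases 2 were higher and 5 lower. Camera adjusted p for these lists was 0.985 and 0.353, and 0.99 and 0.671 with an estimated correlation. The counts of called members do not set the lists of this paragraph apart, since 5520 of all 15070 genes tested were called.

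The lists of other cell types and the remaining lists did not pass camera in the USP27X knockdown. Of 23 mesenchymal and basal genes 2 were higher and 7 lower, or 2 and 8 adjusted over the list alone (camera adjusted p = 0.193, and 0.671 with an estimated correlation). VIM measured 9.58 ± 0.789 CPM in shUSP27x, and the integrin gene ITGA5 rose 2.93-fold (edgeR adjusted p = 0.00123). Of the other lists, cell adhesion and matrix genes had 10 higher and 6 lower of 30 (10 and 7 over the list alone), with a median log2 fold change of 0.47 and a mean of -0.02. Genes of the unfolded protein response and ATF4 had 8 and 3 of 27 (9 and 4), oxidative phosphorylation 2 and 9 of 31, cytosolic ribosomal proteins 3 and 1 of 34 (1 and 1) and cholesterol biosynthesis 0 and 2 of 24. Fibroblast markers had 3 and 1 of 6, blood and endothelial markers 1 and 0 of 5, and basal-like markers 1 and 2 of 10 (1 and 3). Adjusted p with an estimated correlation was 0.637 to 0.985 for these 8 lists. Where no count adjusted over the list alone is given, it equalled that over all genes tested. The total of 5520 called genes fell to 3670 without pGIPZ_2 and to 3151 without shUSP27x_1, and the 1693 that differed from both vectors to 991, 975, 753, 583 and 1012 without pGIPZ_1, pGIPZ_2, pLKO_2, shUSP27x_1 and shUSP27x_2.

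In the USP51 knockdown, against the average of vectors that themselves differed on these lists, luminal genes and BCL2 were higher, and mesenchymal, histone and cell-cycle genes were lower. Against pLKO alone 2 luminal genes were higher, and 4 mesenchymal, 5 histone, 2 G1/S and 1 G2/M genes were lower. VTCN1, an immune checkpoint ligand, rose 38.7-fold, to 75.8 ± 7.13 CPM from 0.941 ± 0.408 in pGIPZ and 4.06 ± 1.74 in pLKO (log2 fold change 5.28, SE 0.29, edgeR adjusted p = 4.03e-05, and 18.8-fold with 0.00111 against pLKO alone). BCL2 rose 3.95-fold, to 47.2 ± 0.532 CPM from 12.7 ± 2.2 in pGIPZ and 11.2 ± 2.42 in pLKO (log2 fold change 1.98, SE 0.18, edgeR adjusted p = 6.12e-04). Against both vectors 1534 genes were higher and 1960 lower on average. Against pLKO alone 214 were higher and 402 lower by edgeR, and 514 and 791 by DESeq2. Against each vector separately 177 were higher and 365 lower. In a fit to the libraries of its own set alone, 11 were higher and 3 lower, or 394 and 563 with a replicate block. Of the genes named here for this knockdown VTCN1, BCL2, CXCL14 and ATP6V0A4 passed in that fit without a block, while most others did not. In data simulated for the comparison with pLKO, edgeR recovered 38 of 100 genes changed 2-fold and 87 of 100 changed 4-fold.

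Further genes that rose against both vectors were CXCL14, a chemokine, 27.1-fold, VTN, the adhesive protein vitronectin, 20.4-fold, HGD, an enzyme of tyrosine breakdown, 19.5-fold, and ADAMTS9, a secreted protease, 8.72-fold (edgeR adjusted p = 2.43e-04, 0.00107, 0.00161 and 9.76e-04). Against pLKO alone VTN rose 9.18-fold (edgeR adjusted p = 0.019). ADAMTS9 reached 55.2 ± 3.72 CPM from 6.04 ± 0.178 in pGIPZ and 6.67 ± 4.18 in pLKO. The proton pump gene ATP6V0A4 rose 10.3-fold. SLC5A8 rose 11.8-fold (log2 fold change 3.56, and 2.75 without shUSP51_1) and TARP 10.2-fold (3.35, and 4.17 without pLKO_1). CXCL14 and ATP6V0A4 overlap genes on the opposite strand.

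The genes that fell most were at 0 counts in both shUSP51 libraries and differed between the vectors as well. HMGA2, an architectural chromatin protein gene of embryonic cells, stood at 30.4 ± 5.85 CPM in pGIPZ and 5.58 ± 4.47 in pLKO and was at least 418-fold and 80.8-fold lower in shUSP51. The neurofilament gene NEFL was at least 213-fold and 73.8-fold lower, the transcription factor genes TCF4 and TBX18 at least 258-fold and 44.1-fold and at least 217-fold and 40.2-fold, and CXorf57 at least 308-fold and 74.2-fold. LRCH2, CCDC8 and CNTN1 were at least 153-fold to 240-fold lower than in pGIPZ and at least 29.7-fold to 39.5-fold lower than in pLKO. Across 176 genes with 3 counts or fewer in shUSP51, at least 2 CPM in pGIPZ and no known opposite-strand overlap, the median level relative to pGIPZ was 0.183 in pLKO, 0.723 in shUSP22 and 0.0143 in shUSP27x. By library it was 0.78 in pGIPZ_1 and 1.22 in pGIPZ_2, and 0.0734 in pLKO_1 and 0.287 in pLKO_2. It was 0.477 in shUSP22_1 and 0.96 in shUSP22_2, and 0 in shUSP27x_1 and 0.0237 in shUSP27x_2. These 176 genes made up 81 of the 365 genes lower than both vectors in the USP51 knockdown and 69 of the 1022 in the USP27X knockdown. Of the genes more than 8-fold lower against pLKO among these, they made up 81 of 160 and 64 of 118.

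**Figure D4:**
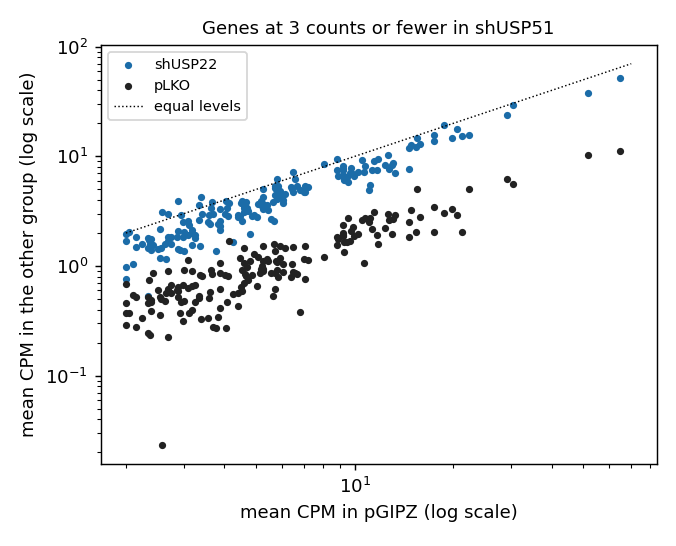
Mean CPM in shUSP22 (blue) and pLKO (black) on the y axis against mean CPM in pGIPZ on the x axis, both on log scales, with 1 point per gene for genes with 3 counts or fewer in shUSP51, at least 2 CPM in pGIPZ and a level above 0 in pLKO. The dotted line marks equal levels; the median level relative to pGIPZ over the 176 genes was 0.723 in shUSP22 and 0.183 in pLKO.

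Mesenchymal and basal genes fell as a list, with 12 of 23 lower and 0 higher, or 13 and 0 adjusted over the list alone (camera adjusted p = 1.52e-07, 0.44 with an estimated correlation and 0.0133 by fry). VIM fell to 1.79 ± 0.353 CPM from 244 ± 52.9 in pGIPZ and 32.1 ± 24.1 in pLKO. The control vectors differed on this list as well: the pLKO to pGIPZ ratio was 0.132 for VIM and 0.154 for CDH2, against the median of 0.183 over the 176 genes above, and the list's median log2 CPM was 1.14 in pLKO_1 and 2.41 in pLKO_2. CAV2, which encodes a caveolin, fell 2.57-fold, to 14.2 ± 5.39 CPM from 36.7 ± 3.8 in pGIPZ and 36.6 ± 1.79 in pLKO (edgeR adjusted p = 0.00293). CAV1 fell 7.03-fold (edgeR adjusted p = 0.00266), and its log2 fold change of -2.81 became -2.19 without shUSP51_1 and -4.02 without shUSP51_2. Basal-like markers, most of which (among them VIM and CAV1) are also in this list, were lower in 4 of 10 and higher in 0 (camera adjusted p = 0.00182, 0.44 with an estimated correlation and 0.016 by fry). Luminal identity genes were higher in 12 of 21 and lower in 0, or 14 and 0 adjusted over the list alone (camera adjusted p = 6.46e-07, 0.44 with an estimated correlation and 0.0163 by fry). TFAP2C, a luminal transcription factor, rose 2.0-fold, to 224 ± 41.0 CPM from 108 ± 5.72 in pGIPZ and 117 ± 13.7 in pLKO, and TFF3 rose 2.82-fold (edgeR adjusted p = 0.00274 and 0.00181), but TFF3 did not pass against pLKO alone (0.0683). Against pLKO alone the median log2 fold changes of the luminal and mesenchymal lists were 0.38 and -1.28. Of 32 estrogen receptor targets 7 were higher and 4 lower, or 8 and 4 adjusted over the list alone (camera adjusted p = 0.309, and 0.806 with an estimated correlation).

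Cell division genes were also lower, with median log2 fold changes of -0.78 for histones, -0.57 for G1/S genes and -0.68 for G2/M genes. Of 21 histone genes 19 were lower, of 31 G1/S genes 21, and of 32 G2/M genes 19 were lower and 1 higher. Adjusted over the list alone 21, 25 and 28 were lower. Camera gave adjusted p of 1.09e-12, 5.28e-11 and 1.82e-08, with an estimated correlation the adjusted p was 0.44, 0.44 and 0.765, and by fry it was 0.0133, 0.0133 and 0.048. TOP2A, a DNA topoisomerase, fell 2.2-fold, to 204 ± 23.5 CPM from 501 ± 23.9 in pGIPZ and 403 ± 71.5 in pLKO (edgeR adjusted p = 0.00238). UHRF1, a DNA methylation cofactor, fell 2.31-fold, POLA1 of DNA polymerase alpha 1.86-fold, HIST1H3H 2.19-fold and CDKN2C 2.15-fold (edgeR adjusted p = 0.00191 to 0.00372). Against pLKO alone 18 histone, 16 G1/S and 6 G2/M genes were lower adjusted over the list alone. Cytosolic ribosomal protein genes were lower in 9 of 34 and higher in 0, or 12 and 0 over the list alone, with a median log2 fold change of -0.29 (camera adjusted p = 8.05e-04, 0.804 with an estimated correlation and 0.0352 by fry).

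In the USP51 knockdown MYC target genes were lower in 5 of 30 (camera adjusted p = 0.011, but 0.111 without pLKO_2), and cholesterol biosynthesis genes were higher in 2 of 24, or 0 over the list alone (adjusted p = 0.0288, but 0.055, 0.258 and 0.092 without pGIPZ_2, pLKO_1 or shUSP51_2). With an estimated correlation the adjusted p was 0.804 for both, by fry it was 0.255 and 0.401, and against pLKO alone camera gave 0.157 and 0.0993. The other lists did not pass camera, with adjusted p of 0.804 to 0.997 with an estimated correlation. Of these, SAGA subunits had 0 higher and 4 lower of 18, with TAF9B down 1.61-fold (edgeR adjusted p = 0.00443). The deubiquitinating module had 0 and 1 of 9, the H2B ubiquitination list 1 and 2 of 19 (0 and 1 over the list alone), cell-cycle inhibitors 0 and 2 of 11, p53 targets 0 and 3 of 24, and oxidative phosphorylation 1 and 3 of 31. Glycolysis and hypoxia genes had 7 and 2 of 30 (7 and 3), the unfolded protein response 4 and 2 of 27, interferon-stimulated genes 4 and 1 of 29 (2 and 1), NF-kB genes 1 and 2 of 16 and immediate early genes 6 and 3 of 25. Apoptosis regulators had 5 and 3 of 24, adhesion and matrix genes 10 and 9 of 30, fibroblast markers 1 and 2 of 6 and blood and endothelial markers 0 and 0 of 5. The median and mean log2 fold change had opposite signs for the module (0.08 and -0.19), p53 targets (0.05 and -0.02), the unfolded protein response (0.06 and -0.04), apoptosis regulators (-0.03 and 0.04) and adhesion genes (0.37 and -0.46). The total of 3494 called genes fell to 2279, 1807, 1478 and 1420 without pGIPZ_1, pGIPZ_2, shUSP51_1 and shUSP51_2. The 542 genes that differed from both vectors became 144, 147, 920, 61, 331, 332, 29 and 82 without pGIPZ_1, pGIPZ_2, pLKO_1, pLKO_2, shUSP22_1, shUSP22_2, shUSP51_1 and shUSP51_2.

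Compared directly, the USP27X and USP51 knockdowns differed in single genes and in the cell division and mesenchymal lists. INHBA was 88.2-fold and GLRA3 32.8-fold higher in the USP27X knockdown (edgeR adjusted p = 1.51e-05 for both). SYNPO2, an actin-binding protein gene, was 17.6-fold lower, at 2.87 ± 0.42 CPM against 50.4 ± 3.26 in shUSP51 (edgeR adjusted p = 4.32e-05), and VTN 15.9-fold lower (adjusted p = 0.00323; log2 fold change -3.99, and -3.36 without shUSP27x_1 and -5.05 without shUSP27x_2). Histone, G1/S and G2/M genes were lower in the USP27X knockdown in 10 of 21, 12 of 31 and 19 of 32 members and higher in 0, or 13, 19 and 30 lower adjusted over the list alone (camera adjusted p = 1.90e-07, 9.22e-08 and 1.29e-16). Mesenchymal genes were higher in 5 of 23, ribosomal protein genes in 10 of 34 and NF-kB genes in 6 of 16, with 0 lower, or 5, 13 and 9 higher adjusted over the list alone (camera adjusted p = 1.71e-04, 3.65e-06 and 3.66e-04). With an estimated correlation the adjusted p of these 6 lists was 0.374 to 0.634. In all 1018 genes were higher and 1084 lower in the USP27X knockdown, a total that fell to 1375, 1397, 1002, 1177, 774 and 1115 without pGIPZ_1, pGIPZ_2, shUSP27x_1, shUSP27x_2, shUSP51_1 and shUSP51_2.

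The USP22 knockdown lies in the other library set, so that its contrasts with the other knockdowns cannot be told apart from the difference between the sets. MIF headed the genes that were higher in shUSP22, at least 4080-fold against shUSP27x and 4860-fold against shUSP51. HMGA2 was at least 399-fold and TCF4 at least 262-fold higher than in shUSP51, and BCL11A at least 71-fold and ETV1 at least 59.9-fold higher than in shUSP27x. DENND1C was at least 125-fold and 150-fold lower in shUSP22 than in shUSP27x and shUSP51. Between the USP22 and USP27X knockdowns 3185 genes were higher and 2771 lower in shUSP22, and 3249 in total differed without shUSP22_2. Between the USP22 and USP51 knockdowns 2319 were higher and 1844 lower, and 2685, 1426, 2148 and 2537 in total differed without shUSP22_1, shUSP22_2, shUSP51_1 and shUSP51_2.

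The USP27X and USP51 knockdowns shared 799 higher and 1317 lower genes, and 107 genes were called in opposite directions. Lists of these sizes drawn independently would share 263 and 382 genes, and 20 simulations of unchanged groups against the same controls shared 0 genes, which holds for groups without effects and sets no bound for lists of these lengths. With the controls split, 87 higher and 263 lower genes were shared when USP27X was set against pGIPZ and USP51 against pLKO, where independent lists would share 43.7 and 91.8. The other split gave 303 and 581, where independent lists would share 117 and 202. Part of the excess in the pooled comparison may come from the shared controls. Both knockdowns also lie in the library set of pLKO, so the difference between the sets enters both in the same direction. Among genes that differed from both vectors in each knockdown, 51 higher and 171 lower were shared. The total of 2116 fell to 1071, 1403, 1032 and 913 without pGIPZ_2, shUSP27x_1, shUSP51_1 and shUSP51_2. By edgeR the USP22 knockdown shared 0 genes in the same direction with either of the others and had 19 and 20 in opposite directions, where independent lists would share 3.26 higher and 1.75 lower genes with USP27X and 1.93 and 1.17 with USP51. DESeq2 gave 5 and 8 shared genes, and setting USP22 against pLKO and the other against pGIPZ gave 3 higher and 2 lower with USP27X and 2 higher and 0 lower with USP51, where independent lists would share 110 and 147 and 82.8 and 116. No gene was called in the same direction in all 3 knockdowns by edgeR. Because shUSP22 lies in the other library set, the difference between the sets enters its fold changes with the opposite sign. That alone lowers same-direction sharing and raises opposite calls, so these counts do not show that USP22 shares no effects with the others. With each knockdown set against the vector of its own set, USP22 had 1 called gene, too few to compare.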

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

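The replicate block within each library set, the restriction to genes with no opposite-strand overlap and the fits to the libraries of 1 set were chosen after the result was seen. A library left out leaves its group with 1 library, which is assumed to vary like the others. Counts of called genes then ranged from 8 to 33 for USP22 against controls, 3151 to 5906 for USP27X, 1420 to 4269 for USP51, 125 to 2570 for pGIPZ against pLKO, 3249 to 6485 for USP22 against USP27X, 1426 to 4724 for USP22 against USP51 and 774 to 2599 for USP27X against USP51. Genes that differed from both vectors ranged from 0 to 1, 583 to 2109 and 29 to 920. Genes shared by USP27X and USP51 ranged from 913 to 2667, by USP22 and USP27X from 0 to 0, and by USP22 and USP51 from 0 to 4. The 28 genes of USP22 became 131 with DESeq2, 270 with the block within sets, 10 among genes with no overlap, 1 with the controls as 1 group, 15 with only knockdown and control libraries, 1 against pGIPZ, 1183 against pLKO, 1 in its own set and 1315 there with a block. For USP27X (5520) the controls as 1 group gave 3082, pLKO alone 1884, its own set 580 and that set with a block 2442. For USP51 (3494) these gave 1049, 616, 14 and 957. The 2036 genes of pGIPZ against pLKO became 1238 with no overlap. The 2102 genes of USP27X against USP51 became 3933 with the block within sets and 746 in their own set. Genes that differed from both vectors became 3123 for USP27X with the block within sets, and for USP51 1061 with DESeq2, 874 with a replicate block and 1644 with the block within sets. Genes shared by USP27X and USP51 became 524 with the controls as 1 group and 350 and 884 with the controls split. Those shared by USP22 and USP27X became 5 with DESeq2, 8 with the block within sets and 5 with a split, and by USP22 and USP51 8, 13 and 2. The G1/S list of USP22 turned to the opposite direction against pGIPZ alone (camera adjusted p = 0.661). Apart from the changes that follow from fewer genes or libraries, the cause was not tested. Deviations of same-numbered libraries from their group means correlated across genes at 0.681, 0.72, 0.303 and 0.221 within the sets and at -0.161 to -0.328 across them. The labels tie the numbers to nothing shared and each group has 2, so they were not used as pairs in the main comparison. A replicate block, over all libraries or within each set, changed no named gene's call against the average of both vectors. Against pLKO alone, the block within sets gave 1718 higher and 2165 lower genes for USP27X and 784 and 1375 for USP51, and brought both targets past the threshold (edgeR adjusted p = 0.0322 for USP27X and 0.0133 for USP51), while a fit to their own set without a block gave 0.169 and 0.181. Of the 252 results on named genes, alternatives kept the call 4964 times, lost it 548 times, gained it 2 times and turned it 0 times. Leaving out 1 library kept 2329 of these calls and lost 190. The fit to the knockdown's own set kept 64 calls and lost 151, that fit with a block kept 161 and lost 54, pLKO alone kept 134 and lost 78, and the controls as 1 group kept 159 and lost 53. Calls lost in the own-set fit include BIK and OLFML3 in the USP27X knockdown (edgeR adjusted p = 0.0622 and 0.109) and VIM, CAV1, CAV2, TOP2A, HGD, VTN, ADAMTS9 and HMGA2 in the USP51 knockdown (0.0632, 0.0922, 0.0982, 0.102, 0.0715, 0.0668, 0.0668 and 0.0819). Of 24 list results they kept it 359 times, lost it 72 times and turned it 1 time, and all 24 were lost with an estimated correlation, 11 with fry and 8 against pLKO alone. Depth limits genes with few counts, such as USP51 at 7 and 8 counts in its knockdown and the genes at 0.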

Other observations

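The tests of overlap counting, of the ratios of genes absent from the knockdowns, of fibroblasts, of the knockdowns as the whole cause, of lost cells and of scaling were chosen after the result was seen, and those of fibroblasts and scaling replaced earlier tests, the first of which passed its bound only with COL1A2 and the second of which compared scalings that hardly differed. LAMC2, a laminin chain of the basement membrane, rose 4.01-fold in the USP27X knockdown, and VWF, an endothelial clotting factor gene, 3.72-fold (edgeR adjusted p = 0.00256 and 0.00557, and 0.0143 and 0.0814 against pLKO alone). HERC5 fell in the USP27X and USP51 knockdowns, 3.35-fold and 4.81-fold, and ISG20 rose 6.86-fold and 2.06-fold. Against pLKO alone the ISG20 rise in the USP51 knockdown did not pass (edgeR adjusted p = 0.429).

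The counts of some genes went with the library sets, with 95 genes near 0 in every library of 1 set. Counting of overlapping genes could account for part of these: 39.3% overlapped an opposite-strand gene, against 23.1% of tested genes, which does not decide it. For the other differences the tables argue against it, since 1238 genes still differed between pGIPZ and pLKO among genes with no overlap. A difference in how the sets were made or counted, and the vectors themselves, cannot be told apart and stay open. No biological explanation was tested.

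A group of 176 genes present in pGIPZ was at 3 counts or fewer in shUSP51 and near 0 in shUSP27x. Their pLKO to pGIPZ ratios had a median of 0.183 and quartiles of 0.144 and 0.224, the upper 1.56-fold above the lower. The other 12239 tested genes at 2 CPM or more in pGIPZ had quartiles of 0.808 and 1.22 around a median of 0.999. A spread this narrow is thus ordinary and does not by itself point to mixed cells. The shared shift is what cells of another kind mixed in differing shares into the cultures might give, while the knockdowns as the whole cause would leave the vectors alike. COL1A1, COL3A1, DCN and LUM were at most 1.82-fold higher in pGIPZ than in shUSP51, against a median of 69.4-fold for the group. COL1A1 and COL3A1, at 0.599-fold and 0.797-fold, argue against fibroblasts, while DCN and LUM, at 1 and 13 counts in pGIPZ, were too low to tell. COL1A2 was left out as 1 of the 95 genes above, and FN1, not among the genes chosen, was 2.17-fold higher. PDGFRA, another listed fibroblast marker, went the other way. It is 1 of the 176 genes, with 79 counts in pGIPZ and 1 in shUSP51. Of 4 markers of HEK293-type packaging cells 2 (NEFM and LIN28B, but not PAX2 or L1CAM) met the prediction, with LIN28B at 64.9 CPM in pGIPZ and 0.0749 in shUSP51. MTAP, held to be deleted in MCF7, was 5.49-fold higher in pGIPZ than in shUSP51. Its pLKO ratio of 0.406 lay above the 95th percentile of 0.293 in the group. MTAP kept 2.88 CPM in shUSP51, however, while the group was chosen near 0 there. Its ratio is therefore not directly comparable with theirs and does not decide. CDKN2A, also held to be deleted and with levels seen beforehand, stood at 23.6 CPM in pGIPZ and 0.296 in shUSP51. Its ratio of 0.212 lay below that percentile and inside the range of the group. The kind of cell, and a part played by the knockdowns or by selection of clones, stay open.

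Cell-cycle and histone genes were lower in the USP27X knockdown. Loss of cells of another kind is argued against as the whole cause: the part lost against pLKO was 0.649 of that lost against pGIPZ at the median of 84 members (quartiles 0.542 and 0.802), above the same ratio in the absent genes, with a median of 0.172 and quartiles of 0.134 and 0.207. A part played by such loss is not excluded, since the control vectors themselves differed on these lists. A scaling factor, which moves all genes of a library alike, is argued against: relative to the median of all tested genes the 84 members stood at 1.11 and 1.33 in the shUSP27x libraries and 2.38 and 2.44 in the pLKO libraries on the log2 scale, a difference of -1.19. Whether a growth state that varies between cultures contributed could not be told. In the G2/M list the shUSP27x libraries differed from each other by 0.661 on the log2 scale, against a fall of 1.29. The pGIPZ, pLKO, shUSP22 and shUSP51 pairs differed by -0.0278, 0.1, 0.122 and -0.294 in that list. The largest difference thus lay inside the knockdown itself and does not show how cultures without this shRNA vary. An effect of the USP27X shRNA, including on other targets, stays open and was not tested.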
